A study of Gallus gallus with 6 samples.

How the data were processed

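Liver total RNA of 3 ALV-J-resistant and 3 ALV-J-susceptible chickens was sequenced, and the groups and bird numbers were taken from the sample titles. The deposited FPKM values were made by the authors. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, Cufflinks and Cuffdiff and the galGal4 build, without saying which step each tool served. The authors also deposited a normalized signal for the same genes and birds, named counts per the file headers. These counts are read here as fragments per gene divided by a size factor per bird. They were described from their values: above 0.1, 99.5% to 99.7% of the values of a bird were whole multiples of 1 step within 0.02 steps, and each step is read as 1 fragment divided by a size factor set by the authors. Between 2 and 6 values per bird lay above 0 and below that limit. The sum of the values over the step gave 6623024, 5809098 and 3831108 fragments in resistant 1 to 3 and 5539784, 4261586 and 4449319 in susceptible 1 to 3. These totals cover the protein-coding genes of the table only. The table held 1 row for each of 14481 gene identifiers, 12178 of them with a symbol. Symbols were matched without regard to case, and genes whose symbol was not in the table were not analysed here. There were 0 columns of other samples. Coordinates are those of the table in galGal4, with starts raised by 1 to count from 1.

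The FPKM values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), resistant minus susceptible, over the 9626 genes with a mean FPKM of at least 0.5. P-values were 2-sided and adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Means and SDs are of FPKM. For genes listed at 0 in a bird each bird's value is given. An FPKM of 0 may be a failed estimate, so it is not read as absence. Gene lists with 5 or more tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Heterophil granule genes, W-chromosome genes, exocrine pancreas genes and skeletal muscle genes had 4, 0, 1 and 4 tested members and were not tested as lists. No counting model was run. The limma and camera tests of the groups, the lists and the rule for named genes were fixed before the data were examined. The alternatives named below as later choices, the permutation test of the mitochondrial share and the tests among the other observations were not. The rule took up to 12 genes per direction with a symbol, a mean FPKM of at least 1 in the higher group and no overlap between groups, by size of change among genes past the threshold and otherwise by smallest unadjusted p. It also took the 4 members with the smallest p of each list described, the virus receptors, and the 2 most abundant members of the yolk, red cell, pancreas and muscle lists. No pancreas gene other than AMY1A was tested. Gene names in the table that are broken words were passed over. Not every gene that the rule took is described. The report says where a gene was named after its values were seen.

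The tests were checked on simulated values with the spread of these birds. In each round 200 of 9626 genes were changed, all drawn from genes with a mean FPKM of at least 10. At the adjusted threshold limma recovered 1.6% of genes changed 2-fold, 24.4% changed 4-fold, 60.4% changed 8-fold and 78% changed 16-fold. It also called a mean of 5.2 unchanged genes per round. Lower genes were never changed and listed 0s were not simulated, so recovery among those was not measured. camera called 33 of 35 lists when each was shifted by 1 log2 unit, and 0 of 1225 tests of unshifted lists. The simulated genes were independent of each other, so this says nothing of false calls that correlated genes give. Birds of a group were compared for duplicate libraries, and their fragments differed by a chi-square of at least 144 per degree of freedom. Genes were tested by identifier, and 77 genes repeated a symbol that an earlier gene of the table already had. Alternatives were another pseudocount, values summed per symbol, a fold threshold, other filters, rescaling by median ratios, quantile normalization, a replicate block, array weights, robust moderation, leaving out each bird, and leaving out chromosomes Z and W. Chosen after the data were seen were the scaled counts in place of FPKM, the Z-to-autosome level of each bird as a covariate, the 4 birds with fragments on chromosome W, a filter of 20 FPKM and 0s treated as missing. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.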

Results

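Liver RNA from 6 chickens was profiled by RNA sequencing. 3 birds were labelled resistant to avian leukosis virus subgroup J (ALV-J), a retrovirus of chickens, and 3 were labelled susceptible to it. Each library is a separate bird per the labels. The labels give no age, sex, breed or infection status. The deposited table held 14481 protein-coding genes with FPKM values (fragments per kilobase of transcript scaled to sequencing depth) and scaled fragment counts. The scaled counts corresponded to between 3831108 and 6623024 fragments per bird. Between 6671 and 9424 genes had an FPKM above 0 in a bird.

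The study asked which liver genes differ in expression between resistant and susceptible birds. Among genes above 0 in all 6 birds, the smallest p belonged to CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor. It had a mean FPKM of 45.3 ± 10.8 (SD, n = 3) in resistant livers and 204 ± 44.0 (SD, n = 3) in susceptible livers. Genes of cholesterol synthesis, xenobiotic metabolism and the mitochondrial genome were, as lists, lower in resistant livers, and interferon-stimulated genes were higher, by camera with a preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.672, 0.672, 0.846 and 0.846 with an estimated correlation) or with fry, and that of interferon-stimulated genes ended without susceptible 2 or resistant 2. No single gene passed the test over all genes. Of 9626 genes tested with limma, 0 were higher and 0 were lower in resistant birds at a Benjamini-Hochberg adjusted p under 0.05. The lowest adjusted p was 0.580, and no other tool was run on single genes. These p-values measure the spread between birds. At an unadjusted p under 0.05, limma counted 231 genes higher and 142 lower, 373 in all, where chance alone gives 481.3. Without resistant 3, susceptible 1 or susceptible 3 the first count was 392, 363 or 359, and without resistant 2 the second was 81. The excess of higher genes turned with the handling of low values: 81 were higher and 105 lower with a filter of 5 FPKM. With a filter of 20 FPKM the counts were 10 and 48, and with 0s as missing 69 and 251, both alternatives chosen after the data were seen. All 3 birds of one group lay above all 3 of the other for 427 genes higher and 383 genes lower in resistant birds. These are 8.41% of the genes tested, where chance gives 10% if no values are tied. Genes listed at 0 in more than 3 birds cannot be counted, so the chance share here is lower.

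Among genes lower in resistant birds with no 0 in any bird, CYP1A1 had a log2 fold change of -2.15 (SE 0.38, 95% interval -3.00 to -1.31), with a limma adjusted p of 0.708. CYP1A1 lies on chromosome 10 from 1938235 to 1941050 on the minus strand in the galGal4 build. TXNDC17, a thioredoxin-like protein, had an FPKM of 15.5 ± 6.04 in resistant and 58.4 ± 16.1 in susceptible birds (SD, n = 3). Its log2 fold change was -1.88 (SE 0.47). ODC1, the first enzyme of polyamine synthesis, had 5.30 ± 4.06 and 25.8 ± 5.96, and a log2 fold change of -2.25 (SE 0.63). CDCA7L had 23.5 ± 24.0 and 80.1 ± 9.81, and a log2 fold change of -2.18 (SE 0.64). The limma adjusted p of TXNDC17, ODC1 and CDCA7L was 0.984. HHLA2, a B7-family surface protein, had FPKM values of 4.20, 6.88 and 0 in the resistant birds and 161, 19.5 and 93.6 in the susceptible birds. PGRMC2, a haem-binding membrane protein, had 2.04, 7.24 and 0 against 17.5, 75.3 and 43.7. TK1, the thymidine kinase of dividing cells, was listed at 0 in the 3 resistant birds and had 5.48, 15.3 and 16.9 in the susceptible birds. KLHL12 was likewise listed at 0 in the resistant birds and had 7.02, 9.37 and 6.41 in the susceptible birds. TAF15, CYTIP and ZNF259 were also lower in each resistant bird than in any susceptible bird, with 1 or 2 resistant birds listed at 0.

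The 12 named genes with the smallest p among those higher in resistant birds were all listed at 0 in 2 or 3 susceptible birds. GNPNAT1, an enzyme of amino sugar synthesis, had an FPKM of 38.7, 51.2 and 99.1 in the resistant birds and of 0, 0 and 3.31 in the susceptible birds. MRPL20, a protein of the mitochondrial ribosome, had 26.4, 35.5 and 15.5 in the resistant birds and was listed at 0 in the 3 susceptible birds. PFDN1, a subunit of the prefoldin chaperone, had 38.9, 5.28 and 43.0 in the resistant birds and was listed at 0 in the susceptible birds. GABARAPL1, an autophagy protein, had 4.48, 13.5 and 29.3, with 0 in the susceptible birds. ACYP2, CTDSP1, IPPK, C20ORF7, CINP, CD99L2, METTL2A and LRRC39 had the same arrangement. GNPNAT1 and MRPL20 had a limma adjusted p of 0.580 and the other 10 genes one of 0.984. Of the 231 genes with an unadjusted p under 0.05 and higher values in resistant birds, 208 were listed at 0 in at least 1 susceptible bird. Of the 142 genes in the other direction, 65 were listed at 0 in at least 1 resistant bird. The libraries differed in how many genes they listed at 0. Among genes with a mean FPKM of 5 to 10, 3.11% and 6.28% were listed at 0 in resistant 1 and 2 and 15.5% in resistant 3. In the susceptible birds these shares were 12.3%, 26.4% and 14.5%. Some 0s stood at genes that every liver uses: ALB, serum albumin, named after its values were seen, was listed at 0 in resistant 2 and susceptible 3 and at 24858 or more in the other birds. An FPKM of 0 is therefore reported only as listed at 0.

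**Figure D1:**
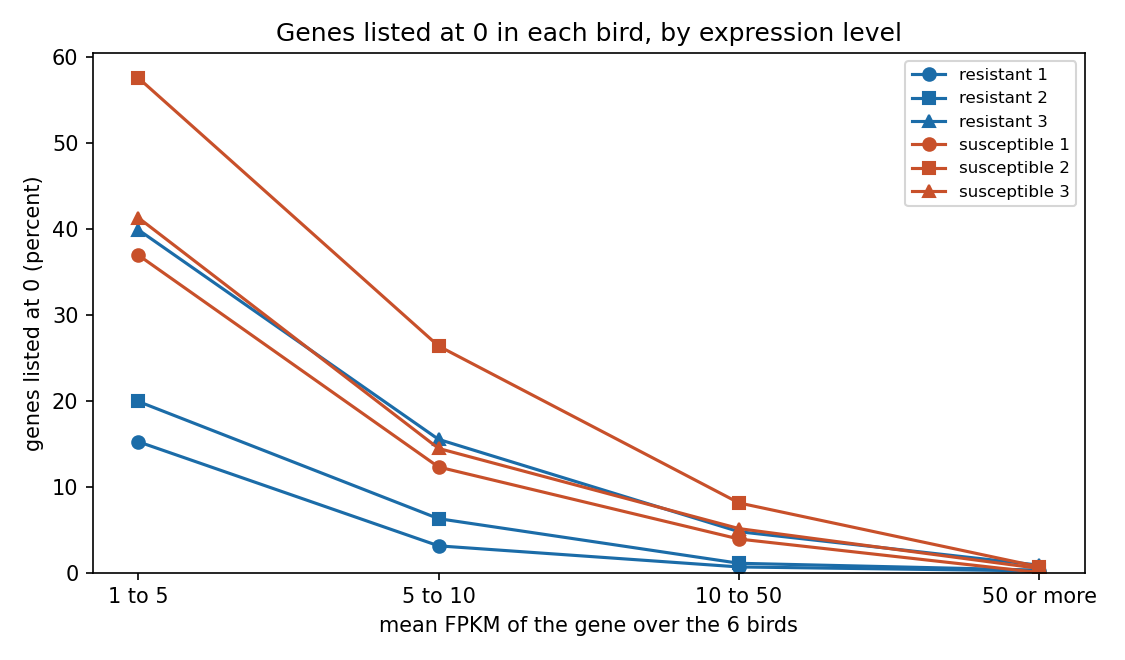
Percentage of genes listed at an FPKM of 0 in each bird (y axis) for 4 classes of genes by mean FPKM over the 6 birds (x axis); each line is 1 bird, blue for resistant and orange for susceptible. In the class of 5 to 10, resistant 1 and 2 lie at 3.11% and 6.28% and susceptible 2 at 26.4%.

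Of the 39 gene lists fixed before the data were examined, 35 had at least 5 tested members. limma's camera with a preset inter-gene correlation of 0.01 called 6 of them at an adjusted p under 0.05, 5 lower and 1 higher in resistant birds. With a correlation estimated for each list, 0 of the 6 calls held, and the lowest adjusted p was 0.672. limma's fry rotation test, which asks whether the members of a list move one way on balance, also called 0 lists. At an unadjusted p under 0.05, xenobiotic metabolism (p = 0.028) and cholesterol synthesis (p = 0.038) stood below the line with an estimated correlation.

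**Figure D2:**
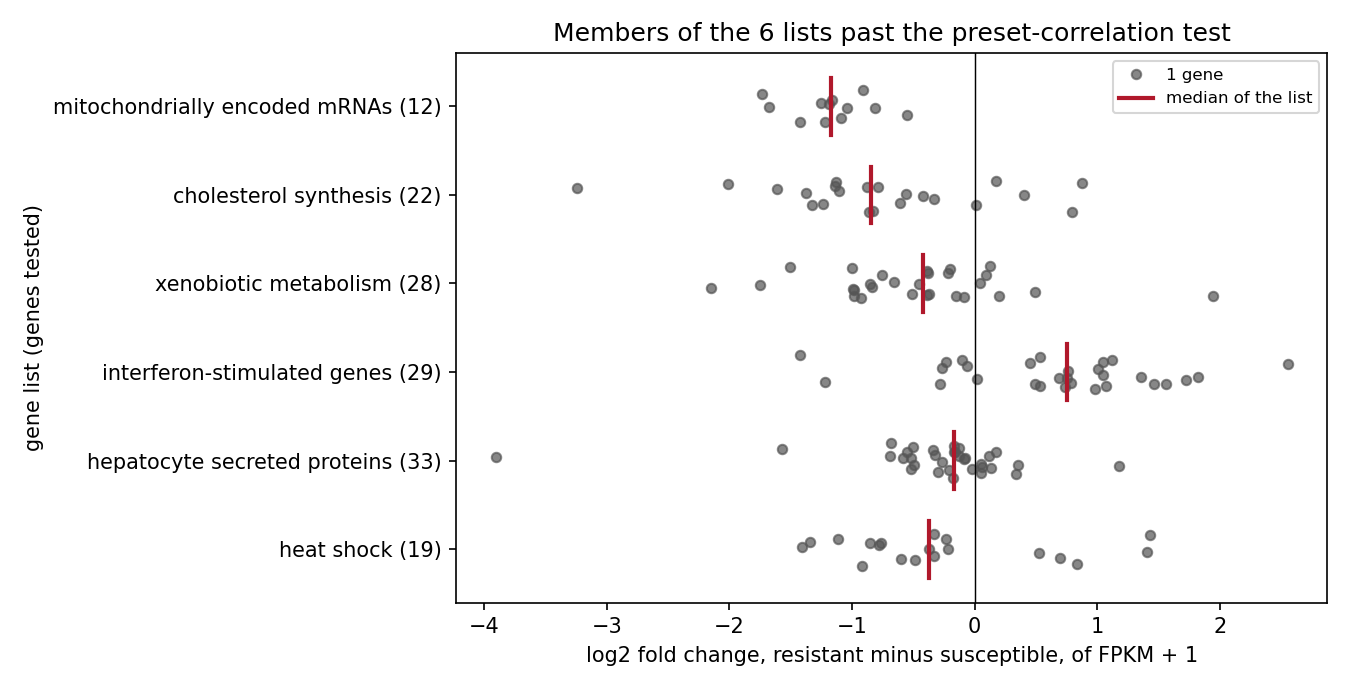
log2 fold change of FPKM + 1, resistant minus susceptible (x axis), of each tested member (grey points) of the 6 gene lists called with a preset correlation (y axis, with the number of genes); red bars are list medians. The medians run from -1.17 for mitochondrially encoded mRNAs to 0.75 for interferon-stimulated genes.

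Cholesterol synthesis genes were lower in resistant livers by camera with a preset correlation, and not with an estimated one (adjusted p = 0.672 with an estimated correlation). Of 22 tested members, 17 had a lower value in resistant birds, and the median log2 fold change was -0.84. LSS, which forms lanosterol, had an FPKM of 46.7 ± 13.2 in resistant and 119 ± 37.5 in susceptible birds (SD, n = 3), a log2 fold change of -1.32 (SE 0.41). FDFT1, squalene synthase, had 37.4 ± 13.7 and 109 ± 76.2, with a log2 fold change of -1.38, and of -0.85 without susceptible 1. That bird lay above the mean of the birds by a median log2 value of 0.88 over the list, against 0.29 and 0.08 in susceptible 2 and 3. FDPS, farnesyl diphosphate synthase, had 34.7, 15.6 and 0 in the resistant birds and 118, 83.3 and 49.2 in the susceptible birds. Several further members are named here after their values were seen. MSMO1 and SREBF2, the latter the transcription factor of the pathway, were lower in every resistant bird than in any susceptible bird, with log2 fold changes of -1.11 and -1.14. That of SREBF2 was -0.74 without resistant 3 and -0.59 in the 4 birds with chromosome W fragments, chosen after the data were seen. SQLE and CYP51A1 had log2 fold changes of -1.23 and -1.13, with 1 resistant bird above the lowest susceptible bird, and that of SQLE was -0.70 without resistant 3. HMGCS1, an early enzyme of the pathway, had overlapping values. Its FPKM was 358, 421 and 2660 in the resistant birds and 999, 414 and 1933 in the susceptible birds. camera gave the list an adjusted p of 9.3e-08 with the preset correlation. 0 of the 22 members passed limma over all genes, and 0 passed when adjusted over the list alone, where the lowest adjusted p was 0.099. At an unadjusted p under 0.05 limma counted 9 members, all lower in resistant birds.

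Genes of xenobiotic metabolism were lower in resistant livers by camera with a preset correlation only (adjusted p = 0.672 with an estimated correlation). Of 28 tested members, 22 had a lower value in resistant birds, with a median log2 fold change of -0.42. CYP1A1 was 53.5, 33.0 and 49.3 FPKM in the resistant birds and 157, 209 and 245 in the susceptible birds. CYP1A4, its neighbour and close relative on chromosome 10, had 5.24 ± 2.27 and 17.1 ± 8.48 (SD, n = 3). How reads shared by CYP1A1 and CYP1A4 were assigned is not given in the sources used here. TIPARP, a further gene induced through the receptor, had 5.30 ± 6.38 and 13.8 ± 1.09, with 12.6 in resistant 1. Its log2 fold change was -1.75, and -1.10 without resistant 3. SULT1C, a sulfotransferase, had 165 ± 46.0 and 311 ± 67.1, a log2 fold change of -0.93 (SE 0.37). EPHX2, epoxide hydrolase, named after its values were seen, had higher values in resistant birds, at 64.9, 34.6 and 11.9 in the resistant birds and 34.4, 14.0 and 0 in the susceptible birds. camera gave the list an adjusted p of 2.9e-05 with the preset correlation. 0 members passed limma over all genes. When adjusted over the list alone, 1 member passed, CYP1A1, with an adjusted p of 0.0062 from limma, and 3 members, all lower in resistant birds, had an unadjusted p under 0.05. That adjustment was made within each of the 35 lists and not across them. With that many lists, chance alone can give such a pass. Over all genes the limma adjusted p of CYP1A1 was 0.708. CYP1A1 also passed over the list alone without each bird in turn, with adjusted p between 0.020 and 0.048. In the 4 birds with chromosome W fragments, an alternative chosen after the data were seen, its adjusted p over the list alone was 0.17. Its log2 fold change there was -2.08, against -2.15 with all birds, and the median of the list was -0.66.

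**Figure D3:**
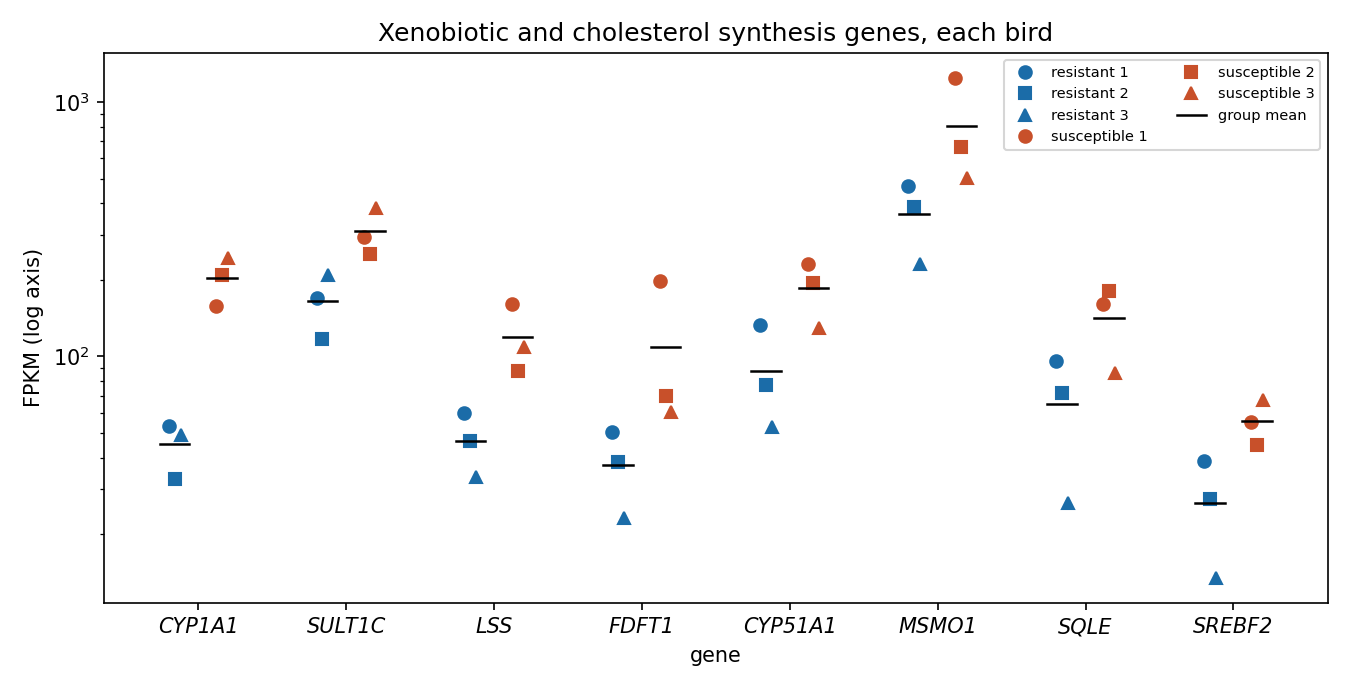
FPKM (y axis, log scale) of 8 genes of xenobiotic metabolism and cholesterol synthesis (x axis) in each of 3 resistant (blue) and 3 susceptible (orange) birds; marker shapes stand for the bird's number and black bars for group means. CYP1A1 was at most 53.5 in the resistant birds and at least 157 in the susceptible birds.

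Messenger RNAs encoded by the mitochondrial genome were lower in resistant livers, though not in each resistant bird, by camera with a preset correlation. The call was lost with an estimated one (adjusted p = 0.846 with an estimated correlation). All 12 tested members had a lower mean log value in resistant birds, with a median log2 fold change of -1.17. ND2 had an FPKM of 705 ± 553 in resistant and 2076 ± 1186 in susceptible birds (SD, n = 3), and ND5 had 495 ± 281 and 1088 ± 367. COX1, named after its values were seen, had 7832 ± 2787 and 11339 ± 3144, with a log2 fold change of -0.55, and of -0.34 without susceptible 3. Several of these genes overlap on the mitochondrial chromosome, ATP8 being given from 9085 to 10706, so their values are not independent. Genes on the mitochondrial chromosome held 6.62% ± 2.64 of all FPKM in resistant and 12.2% ± 4.05 in susceptible birds (SD, n = 3). An exact permutation test of this share, 2-sided, gave p = 0.1, the smallest that 3 birds against 3 allow. This test was not among those fixed before the data were examined, and it uses the same mitochondrial values as the list. Resistant 1 and 2 were at 4.97% and 5.24%, whereas resistant 3, at 9.67%, was close to susceptible 1 and 2, at 9.84% and 9.93%. Susceptible 3 was at 16.9%. camera gave the list an adjusted p of 4.3e-09 with the preset correlation. 0 members passed limma over all genes and 0 when adjusted over the list alone, where the lowest adjusted p was 0.086, and 6 had an unadjusted p under 0.05. Nuclear-encoded genes of oxidative phosphorylation had a median log2 fold change of 0.07 over 46 members, with a camera adjusted p of 0.818.

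Interferon-stimulated genes were higher in resistant livers by camera with a preset correlation, and not with an estimated one (adjusted p = 0.846 with an estimated correlation). Of 29 tested members, 22 had a higher value in resistant birds, with a median log2 fold change of 0.75. CMPK2, a mitochondrial nucleotide kinase, had an FPKM of 70.1 ± 20.8 in resistant and 33.1 ± 30.5 in susceptible birds (SD, n = 3). DHX58, a cytosolic RNA sensor, had 3.55, 5.75 and 1.73 in the resistant birds and 0, 0 and 1.32 in the susceptible birds. IFI27L2 had 115, 106 and 18.1 against 37.2, 0 and 29.5. Mx, an antiviral GTPase named after its values were seen, had 108, 130 and 32.7 against 69.6, 8.15 and 43.2. Some lists of markers of other cells were low in the same bird, and others, such as stellate cell and matrix genes (-0.08) and B and plasma cell markers (0.08), were not. Susceptible 2 lay below the mean of the birds by a median log2 value of -1.27 for interferon-stimulated genes, -1.18 for macrophage, -1.54 for MHC class II, -0.99 for cytokine and -0.83 for endothelial genes. It also had the fewest genes above 0, 6671. Susceptible 2 had the lowest values of CMPK2, IFI27L2 and Mx. camera gave the list an adjusted p of 0.0015 with the preset correlation. Without susceptible 2 the median was 0.23 and the adjusted p 0.30, without resistant 2 they were 0.73 and 0.12, and both ended the call. Without susceptible 2 the log2 fold change of CMPK2 was 0.65, against 1.57 with all birds, and that of Mx 0.49, against 1.36. 0 members passed limma over all genes and 0 when adjusted over the list alone, where the lowest adjusted p was 0.405, and 1 had an unadjusted p under 0.05.

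Secreted hepatocyte proteins and heat shock genes were the other lists called lower in resistant livers, each with adjusted p = 0.846 with an estimated correlation. Of 33 secreted proteins, 24 had lower values in resistant birds, with a median log2 fold change of -0.17. VTN, vitronectin, had an FPKM of 1239 ± 160 in resistant and 1808 ± 98.8 in susceptible birds (SD, n = 3). HRG had 499 ± 111 and 845 ± 403, with a log2 fold change of -0.68, and of -0.32 without susceptible 1, and SERPINF1 had 8.37 ± 4.84 and 25.0 ± 7.09. APOB, the apolipoprotein of very low density lipoprotein, had an FPKM of 5125, 0 and 615 in the resistant birds and 2441, 5359 and 816 in the susceptible birds. Of 19 heat shock genes, 14 had lower values in resistant birds, with a median log2 fold change of -0.37. HSPA8, the constitutive HSP70, had 310 ± 96.1 and 520 ± 94.7, and DNAJA4, a cochaperone, had 15.8 ± 8.15 and 40.1 ± 8.23. DNAJA1 had 49.4 ± 32.3 and 92.9 ± 41.7. Without resistant 2 the log2 fold change of DNAJA1 was -0.35, against -1.11 with all birds, and that of HSPA8 -0.51, against -0.78. HSP90AB1 was listed at 0 in 4 birds and had at most 3.96. camera gave adjusted p of 0.038 for the secreted proteins and 0.042 for heat shock with the preset correlation. 0 members of either list passed limma over all genes, and 0 when adjusted over the list alone, and 1 member of each had an unadjusted p under 0.05. Both calls ended without resistant 1, resistant 2, susceptible 1, susceptible 2 or susceptible 3. The adjusted p then lay between 0.085 and 0.24 for the secreted proteins and between 0.090 and 0.37 for heat shock. Without resistant 3 the calls held, with medians of -0.32 and -0.83. Without susceptible 2 the medians were -0.32 and -0.67, without susceptible 3 that of the secreted proteins was -0.27, and without resistant 2 that of heat shock was -0.17. Both calls also ended under quantile normalization (medians -0.01 and -0.36, adjusted p 0.83 and 0.21) and a filter of 5 FPKM (adjusted p 0.082 and 0.068). That of the secreted proteins ended under median-ratio rescaling (median -0.09, adjusted p 0.090) and a filter of 20 FPKM (adjusted p 0.39), and that of heat shock without chromosomes Z and W (adjusted p 0.099).

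The other 29 lists did not pass camera, with adjusted p from 0.171 to 0.818. Markers of other liver cell types were among them. Macrophage and Kupffer cell markers had a median log2 fold change of 0.64 over 20 genes (adjusted p 0.171), and susceptible 2 lay furthest below the mean of the birds, by a median log2 value of -1.18. This list passed without susceptible 3, with a median of 0.83 and an adjusted p of 0.028. It also passed with a filter of 5 FPKM (adjusted p 0.030), quantile normalization (0.035), the replicate block (0.045) and a filter of 20 FPKM (0.0032). Without susceptible 2 its median was 0.07, and without resistant 3 it was 0.24. Endothelial markers had a median of 0.32 over 20 genes, stellate cell and extracellular matrix genes 0.24 over 31 genes, and T and NK cell markers 0.13 over 19 genes. Bile duct markers had a median of 0.10 and a mean of 0.04 over 12 genes, with camera's direction lower. MHC class I and class II genes had medians of 0.44 and 0.75 over 9 and 6 genes. The unfolded protein response had a median of -0.27 over 26 genes, fatty acid and triglyceride synthesis -0.24 over 27, and complement and coagulation -0.17 over 37. Other lists had a median, mean and camera direction that differed in sign. Acute-phase proteins had a median of -0.10 and a mean of 0.09 over 18 genes, cytosolic ribosomal proteins 0.04 and -0.02 over 61, and proto-oncogenes and tumour suppressors -0.09 and 0.01 over 41. Glucose metabolism had a median of 0.0036 and a mean of 0.08 over 20 genes. In each of these camera's direction was lower. In these lists limma passed 0 members over all genes and 0 when adjusted over the list alone.

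Receptors and host factors of avian leukosis viruses did not differ as a list. The 22 tested members had a median log2 fold change of 0.15 and a mean of 0.01, and camera, which called the direction lower, gave an adjusted p of 0.720. SSRP1, a histone chaperone subunit, had an FPKM of 2.30 ± 1.99 in resistant and 11.9 ± 2.95 in susceptible birds (SD, n = 3), a log2 fold change of -2.14 (SE 0.79). HSPA5, the chaperone of the endoplasmic reticulum, had 192 ± 35.9 and 325 ± 111, a log2 fold change of -0.72 (SE 0.38). TRIM62 had 5.36, 0 and 0 against 2.61, 9.05 and 16.4, and CCDC84 had 2.09, 0 and 11.6 with 0 in the susceptible birds. The gene tvb, receptor of other subgroups of the virus, had 9.32, 2.36 and 6.01 in the resistant birds and 0, 0 and 14.0 in the susceptible birds. BTN1A1 was listed at 0 in the resistant birds and had 0, 0.263 and 5.45 in the susceptible birds. CD320 was listed at 0 in all 6 birds. Not every receptor of these viruses is described here. The limma adjusted p of SSRP1 and HSPA5 was 0.984, 0 members passed over all genes and 0 when adjusted over the list alone, where the lowest adjusted p was 0.468. Without susceptible 3 the log2 fold change of HSPA5 was -0.46.

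The yolk precursor genes VTG2, APOV1 and VTG1 differed widely between birds within each group. VTG2, a yolk precursor made by the liver of laying hens, had an FPKM of 12622, 18820 and 9.65 in the resistant birds and 3345, 11688 and 20.6 in the susceptible birds. APOV1, an oestrogen-induced yolk apolipoprotein, had 24188, 17081 and 12.8 against 2587, 14416 and 51.8. VTG1, named after its values were seen, had 6403, 11100 and 3.19 against 33.3, 5040 and 8.45. Genes on chromosome W, which only hens carry, held 427, 413 and 0 fragments in the resistant birds and 406, 145 and 0 in the susceptible birds. Genes on chromosome Z, relative to autosomal genes and to the mean of the birds, stood at log2 values of -0.19, -0.21 and 0.45 in the resistant birds and -0.24, -0.02 and 0.29 in the susceptible birds. The yolk list as a whole had a median log2 fold change of -0.16 over 10 genes, with a camera adjusted p of 0.416. Markers of blood and of neighbouring tissues overlapped between the groups. CA2 of red cells had 76.3 ± 21.9 and 76.8 ± 36.1 (SD, n = 3), and AMY1A, from the pancreas list, had 65.3 ± 25.7 and 72.0 ± 46.5. Of the 15 pancreas genes in the table only AMY1A was expressed enough to be tested, so its values do not show pancreas tissue. LDB3 and TNNC1 of muscle had 15.9 ± 5.68 and 24.7 ± 5.84, and 8.53 ± 3.91 and 29.6 ± 22.8. TFRC had 10.4, 11.8 and 0 against 5.81, 20.4 and 18.4. CA2 and TFRC were the 2 most abundant of the 10 tested genes of the red cell list. Their values do not measure the blood content of a sample.

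**Figure D4:**
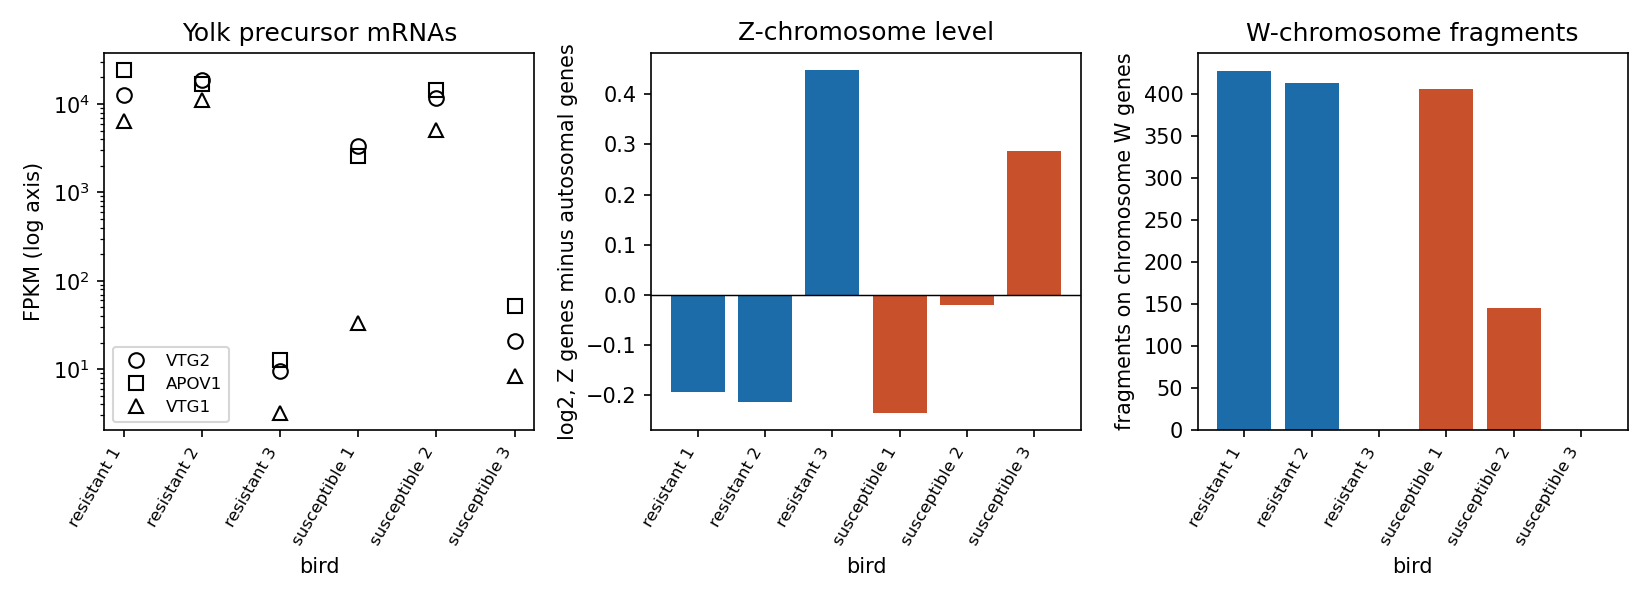
Per bird (x axis), FPKM of 3 yolk precursor genes on a log axis (left), the median log2 level of chromosome Z genes minus autosomal genes (middle) and fragments on chromosome W genes (right); bars are blue for resistant and orange for susceptible birds. Resistant 3 and susceptible 3 had 0 fragments on chromosome W and the lowest yolk precursor values.

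Birds of the same group were no more alike than birds of different groups: the mean correlation within groups minus that between groups was -0.0065. Without susceptible 1, 2 or 3 it was 0.011, 0.0075 or 0.0060. Pearson correlations of log2(FPKM + 1) across the 9626 genes, which are not independent replicates, ran from 0.680 to 0.855 within groups and from 0.669 to 0.799 between groups. The highest value joined resistant 1 and resistant 2. On the 500 genes with the highest variance, the first principal component held 36.2% of the variance. Resistant 3 (-38.4) and susceptible 3 (-38.8) lay at one end of it and the other birds between 8.12 and 39.9. These 2 birds also had the lowest VTG2 and APOV1 values.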

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

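The scaled counts, the Z-to-autosome covariate, the 4 birds with chromosome W fragments, the filter of 20 FPKM and 0s as missing were chosen after the data were seen, and the other alternatives before. In every alternative limma called 0 genes higher and 0 lower in resistant birds. Genes with an unadjusted p under 0.05 numbered 373, and between 58 (filter of 20 FPKM) and 834 (4 birds) in the alternatives. With the replicate block they numbered 458, and deviations from the group mean correlated at 0.012, 0.040 and 0.174 between birds of the same number, so the birds were not treated as pairs. camera called 6 lists, between 3 (without resistant 2) and 9 (without resistant 3) when 1 bird was left out, 7 with the replicate block, 9 with array weights and in the 4 birds, and 0 with the estimated inter-gene correlation. The fry rotation test, which does not compare a list with other genes, called 0. Mitochondrial mRNAs, cholesterol synthesis and xenobiotic metabolism passed in all 19 other camera settings with the preset correlation. All of these settings share the preset value of 0.01, whereas the correlations estimated for these lists were 0.927, 0.166 and 0.056. Passing in them therefore does not show that the calls withstand correlation between members. Interferon-stimulated genes passed in 17, heat shock in 11 and secreted proteins in 10, and no called list changed direction. Of 1366 values of 68 named genes under the alternatives, 1348 kept their direction, and 18 values of 6 genes, none of them called, reversed. No gene passed in any setting, so the side of the threshold could not change. Genes named for having no overlap between groups could not reverse when a bird was left out. The share is therefore no measure of stability, and sizes changed: without resistant 2 the log2 fold change of APOB was -0.31, against -3.91 with all birds. With array weights the log2 fold changes of CA2 and AMY1A were -0.025 and -0.075. In the 4 birds those of CA2 and TFRC were -0.053 and 0.0018. When 1 bird was left out, APOV1 ranged from -1.77 to 4.02, VTG2 from -2.20 to 4.03, CA2 from -0.27 to 0.40, AMY1A from -0.51 to 0.50 and HMGCS1 from -1.26 to 0.20. For the changed results the cause was not tested. A test with edgeR, named before the data were examined for the case of raw counts, was not run, because the deposited counts are scaled. DESeq2 was not run either. Fragments recovered from the scaled counts served for totals and checks, and a counting model on them was not tried. In simulated data with the spread of these birds, limma recovered 24.4% of genes changed 4-fold, all of them with a mean of at least 10 FPKM. Changes of that size can therefore be missed with 3 birds per group, and recovery among lower genes was not measured.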

Other observations

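The tests in this part were chosen after the results were seen, except the tests of the fixed lists on the real groups with the preset correlation, the estimated correlation and fry. Gene Ontology terms carried by the deposited table were tested in the same birds in the same way as the fixed lists. Of 329 terms with at least 10 tested genes, camera with the preset correlation called 1, cholesterol biosynthetic process, which was lower in resistant birds. Its 11 genes had a median log2 fold change of -0.69 and an adjusted p of 0.015, against an adjusted p = 0.999 with an estimated correlation. This term covers the pathway of the fixed cholesterol synthesis list, so its call adds no independent support. The term for defense response to virus had a median of -0.43 over 16 genes (adjusted p 0.987), whereas the fixed list of interferon-stimulated genes had a median of 0.75. BMP signaling had a median of 0.87 over 11 genes (adjusted p 0.987).

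A set of 153 genes, MRPL20 and PFDN1 among them, was above 0 in each resistant bird and listed at 0 in each susceptible bird, and 4 genes (TK1, KLHL12, ATP11A and ENSGALG00000027928) had the reverse arrangement. Lower depth of the susceptible libraries stays open: with resistant 1 thinned to the total of each susceptible bird, 7757, 7338 and 7408 genes were expected at 23 fragments or more and 7436, 6343 and 7245 were observed, differences of -4.14%, -13.6% and -2.20%, while resistant 3, with the fewest fragments of all birds (3831108), was at -1.87%. The pattern is consistent with a wider detection of genes in resistant 1 and 2, whatever the group. The 4 splits of the birds that keep these 2 together gave between 103 and 188 such genes, and the 6 splits that part them between 28 and 51. Since another split gave 188, more than the real one, resistance status and the detection in these 2 libraries cannot be told apart.

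Cholesterol synthesis genes were lower in resistant birds with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.672 with an estimated correlation) and with fry (adjusted p 0.564). Values listed at 0 were argued against as the whole cause, since the 18 members with no 0 in any bird had a median log2 fold change of -0.87, with 16 of them below 0. The sex makeup read from chromosome W fragments did not differ between the groups, since only resistant 3 and susceptible 3 held 0. In the 4 birds with such fragments the median was -0.96, so the lower values did not rest on resistant 3 and susceptible 3. The camera adjusted p there was 8.1e-07 with the preset correlation. In that setting 9 lists passed, so this p does not decide on a cause. The 4 birds were not alike in yolk precursor transcripts. These held 9.94% and 13.4% of FPKM in resistant 1 and 2, and 1.26% and 7.05% in susceptible 1 and 2. Whether this bears on the cholesterol synthesis list was not tested. Resistance status may underlie the difference but was not tested apart from other differences between these 6 birds, and the list also passed in 3 of the 9 other splits, none with a lower p.

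Mitochondrially encoded mRNAs were lower in resistant birds with the preset correlation (adjusted p = 0.846 with an estimated correlation). Yolk precursor transcripts held at most 13.4% of a bird's FPKM. With these taken out of the total, the median log2 fold change was -1.10, against -1.17 with them, and the members lay between -1.65 and -0.48. A share of that size could move the median only a little, so this outcome was set in advance. The FPKM sums also differed between birds, so the step assumes a scaling to the total that these values do not show. The mitochondrial percent may follow the number of genes detected in a library, with Pearson r -0.65 (exact permutation p = 0.143) and Spearman rho -0.89 (exact permutation p = 0.033) over the 6 birds. The yolk percent was the other relation with that number (Pearson r 0.58, exact permutation p = 0.236, Spearman rho 0.54, exact permutation p = 0.297), and the Benjamini-Hochberg adjusted Pearson p of the mitochondrial percent over these 2 relations was 0.236. Without resistant 1 and 2 the mitochondrial r was 0.18, so that relation rests on those birds, and the list passed in the 4 splits that keep resistant 1 and 2 together and in 0 of the 6 that part them (lowest adjusted p 0.291), so status and a feature of these 2 libraries cannot be told apart.

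The 6 birds can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes higher and 0 lower with limma, a count that no split can fall below, and the highest other split gave 1, in 1 direction only, with either group of a split taken as the first. For gene lists the real split gave 6, the highest other split 10, and 5 of the 10 splits gave as many as the real one. Interferon-stimulated genes passed in 3 of the 9 other splits with the preset correlation. In 1 of these the camera adjusted p, 2.0e-05, was lower than the 0.0015 of the real split. Xenobiotic metabolism passed in 1 of the 9, with a camera adjusted p of 0.027.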
